A study of Penicillium oxalicum with 6 samples.

How the data were processed

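RNA sequencing data of Penicillium oxalicum mycelium were used, 3 libraries of a POX_a00954 mutant and 3 of the PoxKu70 strain. Per the labels' protocols, spores from plates kept for 4 days at 28 °C were grown for 24 h on glucose and transferred for 24 h to raw-starch medium, RNA was extracted with Trizol, poly(A) RNA was enriched with oligo(dT) beads, and random-primed cDNA was made into circularised single-stranded DNA libraries. That protocol describes no step that marks the strand. Per the submitters' processing notes, bcl2fastq and HISAT2 were used, without versions. The counting tool, genome build and annotation are not given in the sources used here. The authors deposited 1 file per library, with FPKM per gene (fragment numbers divided by transcript length and by the mapped total of the library) to 2 decimals, per the file headers. FPKM carries the total of each library in its denominator, so that a very abundant gene lowers all others, and no scaling between libraries is recorded.

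Gene IDs are POX locus tags. Of the 9822 IDs, 9718 matched the locus tags of the RefSeq table of P. oxalicum HP7-1 (assembly ASM172317v3), and 104 did not. That table gives no symbols other than the locus tags and no products. It was used for which genes adjoin each other and for the chromosome of each ID letter, and no coordinates are given because the build behind the files is not stated. The lists of starch, cellulose and other pathway genes fixed beforehand were defined on product names and were therefore not used, and no list result is reported.

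The FPKM values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with genotype as the only term and all 6 libraries in the fit. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 8448 in all. A further 767 genes had lower means and 607 were at 0 in every library. The threshold was a Benjamini-Hochberg adjusted p of 0.05, with a second count at an absolute log2 change of at least 1. A fold change on the log2(FPKM + 1) scale understates changes of low genes, and folds of means are plain ratios of mean FPKM. Single genes were also compared by exact two-sided permutation tests, for which 3 against 3 libraries cannot go below p = 0.1. Runs of at least 4 consecutive tested IDs on one ID letter with the same called direction were counted and compared with 10000 permutations of the calls.

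Before the data were examined, the test, the filter, the alternatives and the rule for named genes were fixed. The rule named POX_a00954, POX_c03583, the 2 IDs on either side of POX_a00954, and, because IDs could not be matched to names, only the 2 largest rises and the 2 largest falls among called genes with a mean of at least 10 FPKM and no overlap between the groups. Other genes and regions were chosen after their values were seen and are marked so. Simulated data for this comparison were made from the parent means and replicate spread of the same 8448 genes. Changes were planted only in genes above 10 FPKM in the parent. Of these, 75 of 100 genes changed by 1 log2 unit and 95 of 100 changed by 2 were recovered, with 4 false calls. Far fewer genes were changed there than the 60.5% called in the data. These counts therefore do not give the number of false calls in the data or the recovery of low genes.

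The files used here hold FPKM and no counts, so no count model, counting interval or detection limit was used. The relative depth of the libraries was estimated from genes listed at 0 in at least 2 libraries, whose values between 0.4 and 4.0 FPKM step by whole reads (Python 3.11.15, numpy 2.4.6). After that correction, 72.7% of 227 such values lay within 0.1 of a whole multiple of the gene's lowest value, against 11.1% without it. The correction was fitted to low values of the same genes, so this gain is in part built in and is no separate check. The estimated mean depth of the parent libraries was 1.45 times that of the mutant libraries, so low values were less precise in the mutant.

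Titles carry replicate numbers 1 to 3 in both strains. Whether equal numbers pair the samples was checked from deviations from the strain means, and they were not treated as pairs. Alternatives were pseudocounts of 0.1 and 5, no filter and a minimum mean of 5 FPKM, median-ratio, quantile and TPM scaling, eBayes without trend or with robust estimation, a replicate block, and leaving out each library. Figures were drawn with matplotlib 3.10.9.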

Results

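Gene expression was measured by RNA sequencing in mycelium of Penicillium oxalicum, a filamentous fungus that secretes plant-polysaccharide-degrading enzymes. A mutant of POX_a00954, one of a pair of transcription factor genes named in the series title, was compared with PoxKu70, the strain whose genotype the labels give as wild type. The strain carries the name of Ku70, a DNA end-joining protein; fungal strains lacking it are commonly used as parents for gene replacement, and PoxKu70 is called the parent here. Both strains were grown for 24 h on glucose and then for 24 h in medium with raw starch as the only carbon source. There were 3 libraries per strain, 6 in all. Each library listed FPKM values for 9822 genes. The FPKM sums of replicates 1 to 3 were 1025654, 1076733 and 1066350 in the parent and 1373034, 1338218 and 1409899 in the mutant. The number of reads per library is not known from FPKM values. The steps between low values placed the parent libraries at 1.7, 1.9 and 1.5 times the depth of mutant replicate 1, and mutant replicates 2 and 3 at 1.4 and 1.1 times.

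Libraries of one strain resembled each other far more than libraries of the other strain. Across the 8448 tested genes, Pearson's r of log2(FPKM + 1) lay between 0.965 and 0.980 for pairs within a strain and between 0.750 and 0.808 for pairs across strains. These correlations are across genes, which are not independent replicates. The first principal component held 85.6% of the variance and separated the strains. No 2 libraries held the same values. The labels do not say whether the 3 libraries of a strain came from separate cultures, so all p-values below measure the spread between these libraries only, which may be technical.

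The targeted gene came first, as a check of the labels. POX_a00954 was lower in the mutant than in the parent, but it was not absent. Its level was 333 ± 93.7 FPKM (SD, n = 3) in the mutant and 746 ± 85.4 FPKM (SD, n = 3) in the parent, so that the mutant retained 44.7% of the parent's level. All 3 mutant libraries, at 283, 275 and 441 FPKM, lay below all 3 parent libraries, at 716, 679 and 842 FPKM. The log2 change was -1.19 (SE 0.20) with an adjusted p of 0.0014 in limma with Benjamini-Hochberg adjustment. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. The labels call the strain a mutant without saying which part of the gene was altered, and a gene-level value does not show where along the gene the remaining reads lay.

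The series title names mutual regulation between POX_a00954 and a second transcription factor gene, POX_c03583, and the comparison addresses one side of it, the level of POX_c03583 when POX_a00954 is mutated. POX_c03583 was less abundant in the mutant, at 94.7 ± 9.08 FPKM (SD, n = 3) against 186 ± 34.7 FPKM (SD, n = 3), or 50.9% of the parent's level. Its log2 change was -0.96 (SE 0.16; limma, adjusted p = 0.0014), and the 3 mutant libraries lay below the 3 parent libraries (exact permutation p = 0.1). The reverse side, POX_a00954 in a POX_c03583 mutant, was not analysed here. The fall of both genes passed the threshold under all 17 alternative settings, with log2 changes from -1.57 to -1.07 for POX_a00954 and from -1.33 to -0.82 for POX_c03583. Falls were common, however, since 2532 of the 8448 tested genes were called lower in the mutant. Passing the threshold therefore does not by itself single out either gene or show that POX_a00954 regulates POX_c03583.

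**Figure D1:**
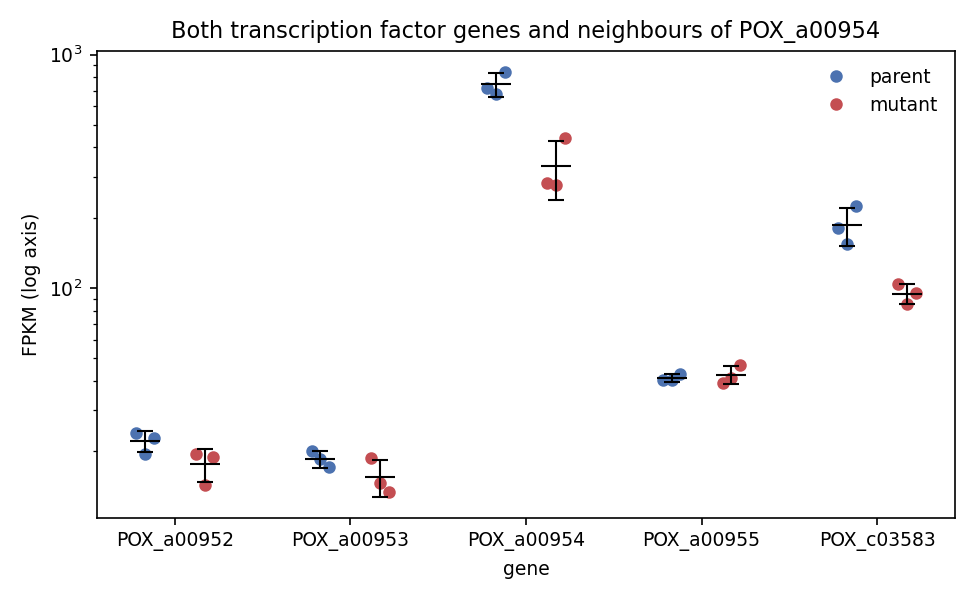
FPKM (log axis) of POX_a00954, POX_c03583 and 3 genes adjoining POX_a00954, with 1 point per library (blue, parent; red, mutant) and black bars for the mean ± SD of 3 libraries. The mutant points of POX_a00954 and POX_c03583 lie below all parent points, with means of 333 against 746 FPKM and 94.7 against 186 FPKM.

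The genes beside POX_a00954 did not pass the threshold. POX_a00952 was at 17.6 ± 2.79 FPKM in the mutant and 22.1 ± 2.32 FPKM in the parent (SD, n = 3 each; limma, adjusted p = 0.11). POX_a00953 was at 15.6 ± 2.78 and 18.6 ± 1.54 FPKM (SD, n = 3 each; limma, adjusted p = 0.20). POX_a00955 was at 42.5 ± 3.8 and 41.2 ± 1.56 FPKM (SD, n = 3 each; limma, adjusted p = 0.80), and POX_a00956 was listed at 0 in all 6 libraries. With every library rescaled to the same FPKM sum (TPM), POX_a00952, POX_a00953 and POX_a00955 were lower in the mutant past the threshold, with log2 changes of -0.67, -0.60 and -0.33. That scaling moved the median of all genes by -0.35, which is close to the change of POX_a00955.

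The mutation went with changes across much of the transcriptome. Of the 8448 tested genes, 5107 (60.5%) passed an adjusted p of 0.05 in limma, 2575 higher and 2532 lower in the mutant. By at least 1 log2 unit, 1308 genes rose and 1195 fell. By at least 4 log2 units, that is 16-fold on the log2(FPKM + 1) scale, 116 rose and 89 fell. The median log2 change of all tested genes was -0.0089. The groups did not overlap for 68.1% of tested genes, where chance gives 10%. With TPM scaling, which followed the larger FPKM sums of the mutant libraries, the split was 1655 higher and 3911 lower, so that 29.7% of the calls were rises.

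The 2 largest rises among genes averaging at least 10 FPKM took genes from low or middling levels to high abundance, and the 2 largest falls took abundant transcripts to below 1 FPKM. POX_b03265 rose from 25.6 ± 8.6 FPKM in the parent to 9228 ± 1523 FPKM in the mutant (SD, n = 3 each), a 361-fold higher mean and the 10th highest level in the mutant. Its log2 change was 8.49 (SE 0.26; limma, adjusted p = 2.079e-07). POX_f08010 rose from 3.03 ± 0.61 to 908 ± 234 FPKM (SD, n = 3 each), with a log2 change of 7.79 (SE 0.22; limma, adjusted p = 1.032e-07). In the other direction, POX_d05671, the 15th most abundant transcript of the parent at 6038 ± 874 FPKM, was at 0.43 ± 0.10 FPKM in the mutant (SD, n = 3 each). Its log2 change was -12.03 (SE 0.14; limma, adjusted p = 1.976e-09). POX_d04867 fell from 3494 ± 208 to 0.69 ± 0.11 FPKM (SD, n = 3 each), with a log2 change of -11.02 (SE 0.12; limma, adjusted p = 1.905e-09). The pseudocount of 1 understates the last 3 of these changes, since one strain was near or below 3 FPKM.

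The most abundant transcript of the mutant came from a gene that was far less abundant in the parent. POX_a00166, singled out after its values were seen, rose from 2314 ± 448 FPKM in the parent to 121763 ± 20161 FPKM in the mutant (SD, n = 3 each), a 52.6-fold higher mean (log2 change 5.72, SE 0.20; limma, adjusted p = 3.454e-07). Quantile normalization, which gives all libraries the same top value, lowered its log2 change to 4.20. It ranked 56th in the parent and 1st in the mutant. It made up 7.18%, 9.80% and 9.61% of the FPKM sum of mutant replicates 1 to 3, against 0.18%, 0.21% and 0.26% in parent replicates 1 to 3. Part of the difference in FPKM sums between the strains therefore came from this gene. The second most abundant transcript of the parent, POX_c04726, also singled out afterwards, went the other way, from 16673 ± 3106 to 69.4 ± 14 FPKM (SD, n = 3 each; log2 change -7.89, SE 0.20; limma, adjusted p = 7.642e-08).

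**Figure D2:**
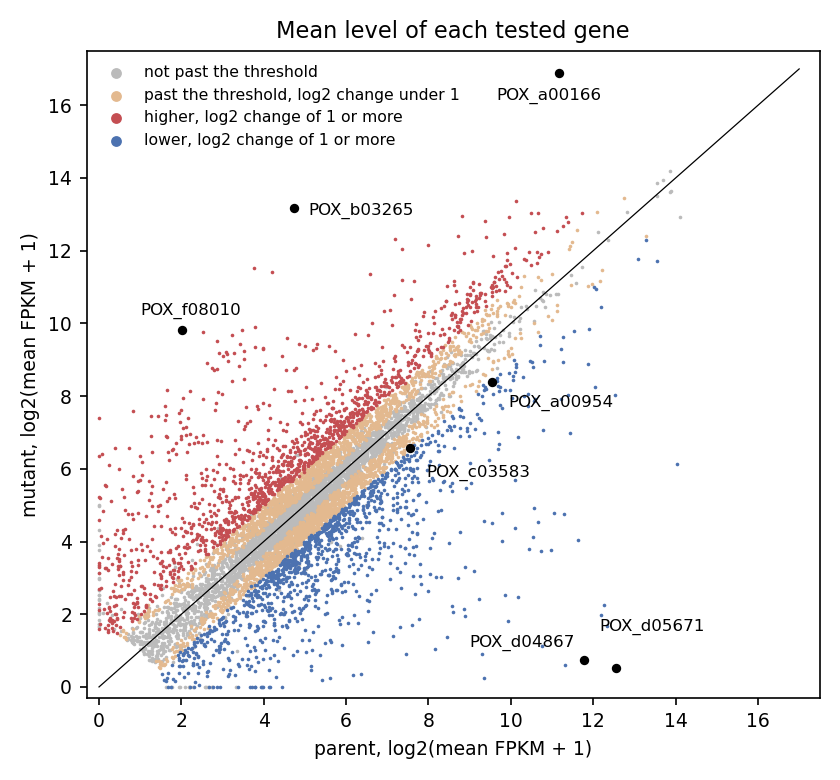
Mean level of each of the 8448 tested genes, log2(mean FPKM + 1) of 3 parent libraries (x axis) and of 3 mutant libraries (y axis), coloured by the limma call; the line marks equal levels and black points are named genes. POX_a00166 lies at the top of the mutant axis, POX_b03265 and POX_f08010 far above the line, and POX_d05671 and POX_d04867 at the bottom.

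The sets of most abundant transcripts overlapped in part. Of the 100 most abundant genes of the parent, 46 were among the 100 most abundant of the mutant. In all, 31 genes were at 10 FPKM or more in every mutant library and under 1 FPKM in every parent library, and 15 genes showed the opposite. Changes were found at every level of expression. Among the 2113 tested genes with the lowest means, 51.4% changed, with 453 rises and 633 falls. Among the 2112 with the highest means, 68.5% changed, with 932 rises and 514 falls.

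A part of the changed genes lay in runs along the chromosomes, and these runs were more numerous than with permuted calls. The comparison was planned because genes of one pathway often adjoin each other in filamentous fungi. There were 198 runs of at least 4 consecutive tested genes that all changed in one direction, 101 of rises and 97 of falls. They held 995 of the 5107 changed genes. Permuting the calls over the tested genes gave 97.9 ± 8.98 runs (SD over 10000 permutations) and never more than 131 (permutation p = 0.0001, the smallest they can give, one-sided). Counting only changes of at least 1 log2 unit left 43 runs, where permutations gave 6.95 ± 2.61. The number of runs fell to 122 without mutant replicate 2, without parent replicate 1 or without parent replicate 3. Fewer genes were called in these fits, at 4341, 4427 and 4415. Permuted calls then gave means of 55.5, 58.6 and 58.6 runs, and never more than 79, 80 and 81 in 1000 permutations each. Neighbouring genes can share reads where their transcripts overlap, and the counting method is not given in the sources used here.

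The longest run spanned 22 adjoining genes, POX_c04232 to POX_c04253, all of which rose by at least 1.28 and at most 6.61 log2 units. Their summed level rose 46.5-fold, from 121 ± 9.71 to 5649 ± 2122 FPKM (SD, n = 3 each), and the most abundant of them, POX_c04240, averaged 6.27 FPKM in the parent and 724 FPKM in the mutant. The run from POX_a00747 to POX_a00762 held 16 genes that were already expressed in the parent and rose 10.5-fold in sum, from 5652 ± 1588 to 59612 ± 9602 FPKM (SD, n = 3 each). Its most abundant member, POX_a00754, rose from 1113 to 10530 FPKM. The 12 tested genes from POX_c04511 to POX_c04523 rose 83.4-fold in sum, from 32.9 ± 4.5 to 2746 ± 583 FPKM (SD, n = 3 each). These regions were named after their values were seen, by their length.

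Among runs of falls, the 15 genes from POX_c04718 to POX_c04732 dropped from a summed 23088 ± 3334 FPKM in the parent to 383 ± 44.6 FPKM in the mutant (SD, n = 3 each), 60.3-fold lower. This run included POX_c04726, which made up most of the parent's sum. The 16 tested genes from POX_f08114 to POX_f08130 fell 5.89-fold in sum, from 1158 ± 107 to 197 ± 28.2 FPKM (SD, n = 3 each), with single log2 changes from -5.82 to -1.39. A further 10 genes close to the first of these regions, POX_c04744 to POX_c04753, fell 3.38-fold in sum, from 2842 ± 186 to 842 ± 187 FPKM (SD, n = 3 each). The files and the reference table give no product or gene name for any of these loci, so the levels of amylase, glucoamylase or other enzyme classes were not analysed here.

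**Figure D3:**
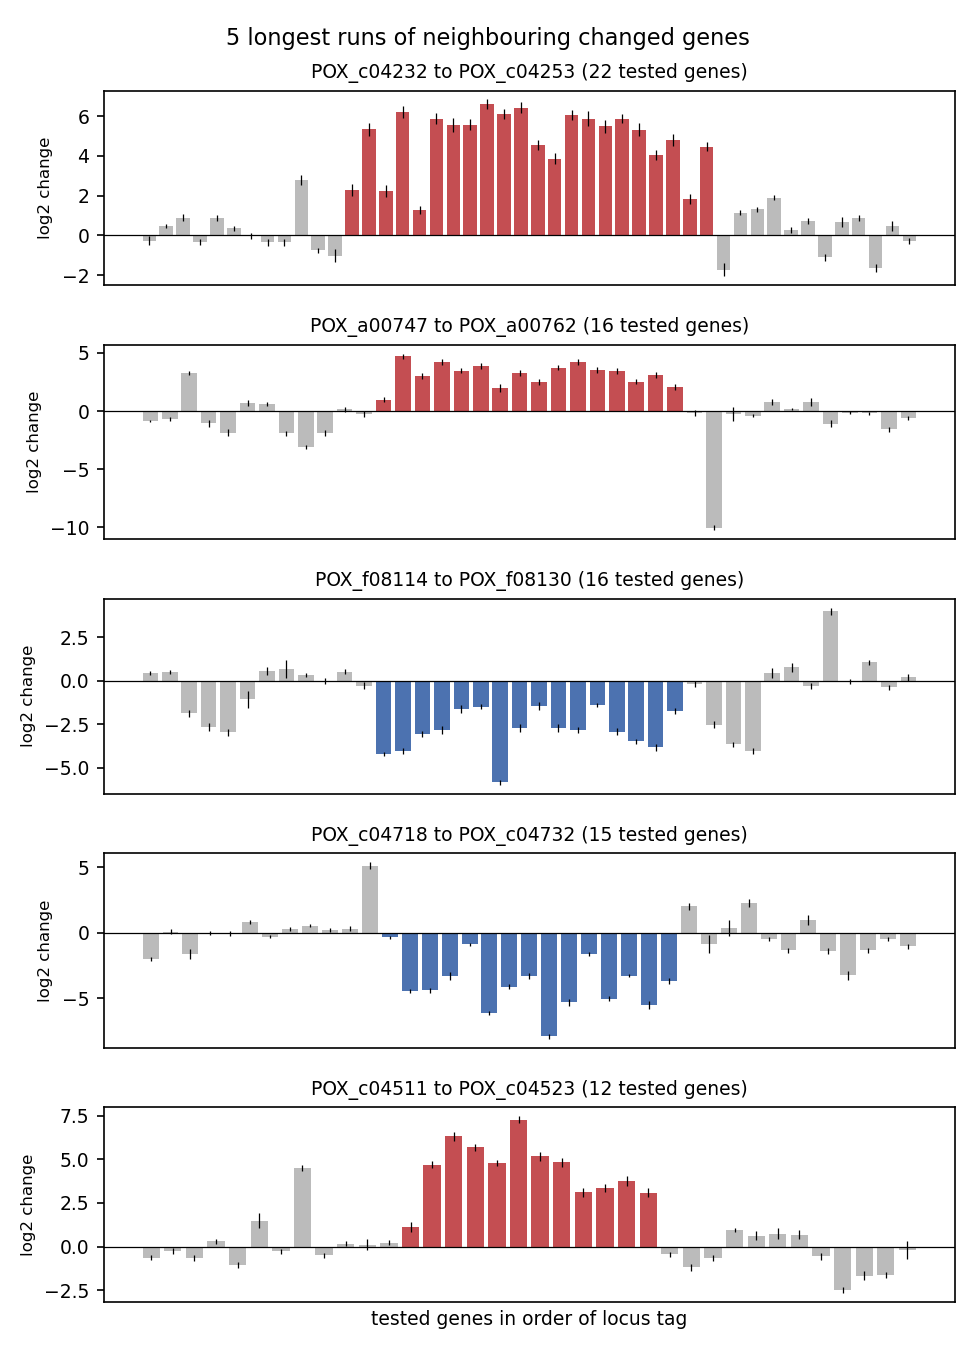
Log2 change (mutant minus parent, on log2(FPKM + 1)) of each tested gene in locus-tag order for the 5 longest runs, with 12 tested genes on either side in grey; red bars are runs of rises, blue bars runs of falls, and lines are ± 1 SE from limma. The bars of the 22-gene run from POX_c04232 reach 6.61, while the flanking genes vary in sign.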

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

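The log2 changes of POX_a00954, POX_c03583, POX_a00166, POX_b03265, POX_f08010, POX_d05671 and POX_d04867 kept their direction and stayed past the threshold in all 17 alternatives, that of POX_a00166 at 4.20 under quantile normalization and 5.34 to 5.87 under the others. The count of changed genes ran from 4341 to 5119 when each library was left out and from 4751 to 5566 over the other settings. No gene called in the main fit was called in the opposite direction in any of them. Changes of sign that did not pass the threshold were not counted. TPM scaling shifted the median log2 change by -0.35 and moved the split to 1655 higher and 3911 lower, or 828 and 1923 at a log2 change of at least 1. POX_a00955 then reversed to -0.33. It ranged from -0.030 to 0.090 when each library was left out (-0.030 without mutant replicate 3). IDs with the letter u are called unplaced here, because that letter stands for none of the chromosomes. POX_a00955 was -0.22 under TPM scaling without POX_a00166 and the unplaced IDs, a setting chosen after seeing the data that gave a median shift of -0.25. Under that setting POX_a00952 and POX_a00953 were lower past the threshold, at -0.57 and -0.50 (limma, adjusted p = 0.011 and 0.025). POX_a00955 was not past it (limma, adjusted p = 0.12). The TPM shift follows from the larger FPKM sums of the mutant libraries. Runs numbered 122 to 188 when each library was left out, with the longest at 22 genes each time, but 297 under TPM scaling and 254 under TPM scaling without POX_a00166 and the unplaced IDs. They numbered 436 for runs of 3 or more and 43 for changes of at least 1 log2 unit, by construction of those settings. Replicate numbers did not pair the samples: deviations of equal-numbered libraries correlated at -0.06, -0.0029 and 0.15, and 2 of 6 libraries correlated best with their own number. A replicate block gave 5103 changed genes, 4922 of them among the 5107. Count models on recovered reads and the tests of pathway lists were not run, for want of counts and of product names. Depth limits values near or below 1 FPKM, which rest on few reads, more so in the mutant.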

Other observations

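All tests of chromosome ends and whole chromosomes, and the tests of mixed RNA, mislabelling, a missing DNA segment, changes by expression level and the share of changes in the rarer direction, were chosen after the results were seen; TPM scaling itself was planned, and the splits of the libraries and the count of local peaks within runs were set before their values were seen.

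Changed genes were more frequent near the ends of the chromosomes. Among the 480 tested genes that are the 30 outermost at either end of chromosomes I to VIII in locus-tag order, 44.2% changed by at least 1 log2 unit, against 28.8% elsewhere. Rotating the calls along the genome, which keeps neighbours together, gave p = 0.0022 (permutation by all 8448 rotations, two-sided; adjusted p = 0.0051 over 3 tests, with falls and rises taken apart as the others). None of the 5 longest runs reaches into these windows, so leaving out their genes (permutation by rotation, p = 0.0014) could only widen the contrast. Shorter runs do lie in the windows, such as POX_c04744 to POX_c04753, where 9 of 10 genes fell by at least 1 log2 unit. How much of the share at the ends such runs carry was not tested. Falls made up 24.8% of genes at the ends against 13.5% elsewhere (permutation by rotation, adjusted p = 0.0051 over the same 3 tests), and rises 19.4% against 15.2% (adjusted p = 0.086); the difference between falls and rises was not tested. With the 20 or the 50 outermost genes the share was 46.9% or 40%. No chromosome as a whole stood apart in either direction; chromosome VIII came nearest among falls with 81 of 428 genes (permutation by rotation, p = 0.095, adjusted p = 0.93 over 16 tests).

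Opposite changes stood close together in places. POX_a00764, with a mean of 4891 FPKM in the parent and 3.76 FPKM in the mutant (log2 change -10.03, SE 0.24; limma, adjusted p = 6.502e-08), has the next locus tag but one after the run of rises from POX_a00747 to POX_a00762. Of the IDs with the letter u, called unplaced here, POX_u09930 was the most abundant transcript of the parent and varied within both strains. It was at 2646, 19010 and 1697 FPKM in mutant replicates 1 to 3 and 26592, 20076 and 6325 FPKM in parent replicates 1 to 3. POX_u09935 had 43.3, 1231 and 29.1 FPKM in the same mutant libraries and 1292, 1022 and 117 FPKM in the parent libraries. Neither passed the threshold (limma, adjusted p = 0.12 and 0.22), and neither ID is in the reference table.

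The mutant kept 44.7% of the parent's POX_a00954 level. RNA of the parent mixed into the mutant libraries would keep other abundant parent transcripts at a like share, but 76 of the 1651 genes averaging at least 100 FPKM in the parent were below 10% of that level in every mutant library. A single mislabelled library is argued against by the lowest correlation within a strain, 0.965, which lay above the highest between strains, 0.808. A candidate explanation that stays open is a mutated locus that is still transcribed in part, and reads of a similar sequence elsewhere also stay open, since gene-level values hold no position along the gene. A partial loss of expression as a biological property of this strain was not tested.

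The runs of neighbouring changed genes may reflect regulation of gene clusters or of chromatin regions, a hypothesis that these data do not test directly. Reads of 1 changed gene counted on its neighbours were predicted to give a single peak per run. In the 5 longest runs, 23 genes lay above their neighbours in the strain with the higher values. Genes at the end of a run were compared with 1 neighbour only. FPKM is divided by transcript length, so reads shared between neighbours need not give a smooth profile, and this count does not decide the question. A DNA segment missing from the strain with the lower values would leave its genes at or near 0. All 81 members (100%) had a value above 0 in every library of that strain, and in 4 of the 5 longest runs 63 of 69 members (91.3%) were at 1 FPKM or more in each of these libraries. In the run from POX_c04511 to POX_c04523 only 4 of 12 members (33.3%) were. Stray reads of the mutant in the parent libraries are bounded by POX_b03265. Of the 418 genes outside the run averaging at least 500 FPKM in the mutant, it kept the lowest share. That share was at most 0.34% of its mutant mean in any parent library. All 12 members of the run kept more than that share of their own mutant means in every parent library, the lowest 0.39%. The margin was narrow for the lowest, and values below 1 FPKM rest on few reads. These values lean against a missing segment there but do not settle it. With 10 splits of the 6 libraries a share under 0.05 cannot be reached. The real split gave 198 runs and the highest other split 0, so only the real split itself reached the real value. Every other split puts both strains in each group, which widens the spread within groups, so this contrast decides nothing.

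In the mutant 60.5% of tested genes changed, while the RNA of POX_a00954 itself fell by 1.19 on the log2 scale. That fall does not show how much of the gene's function was lost. A few abundant genes shifting all others by a shared factor would move them one way, but at least 30.1% of the changes of 1 log2 unit or more lay in the rarer direction as reported and under both TPM scalings, the lowest share being that of TPM scaling. TPM scaling moved the median log2 change by -0.35, and a shift of that size could not by itself give changes of 1 log2 unit. The share in the rarer direction is therefore no test of such a shift. Smaller changes, where it would matter, were not part of that share. Among all calls under TPM scaling, 29.7% were rises. TPM scaling kept the call and direction of 82.0% of the called genes, so single calls do depend on the scaling. Fewer reads in the mutant libraries would place calls among low genes, but 68.5% of the 2112 genes with the highest mean FPKM changed. The 10 splits of the libraries are too few for a share under 0.05. The real split gave 5107 genes and the highest other split 1, so only the real split itself reached the real value. Every other split puts both strains in each group, which widens the spread within groups, so this contrast decides nothing. The genotype, the difference that the design names, was the only term compared. Anything else that the 3 libraries of a strain shared, such as a culture, cannot be told apart from it here.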
